A study of Homo sapiens with 18 samples.

How the data were processed

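The data are 18 SLAM-seq libraries of HEK293T cells that express Cas9, with a control guide RNA or a guide against DHX29, taken after 0, 3 or 6 h of uridine chase, with 3 replicates in each of 6 groups. Per the labels' protocols, RNA was labelled with 25 µM 4-thiouridine for 24 h, chased in 2.5 mM uridine and treated with iodoacetamide, and libraries were made with a QuantSeq 3′ kit. The deposited table holds whole-number read counts per 3′ UTR interval and library, not normalised, as its values show. Per the submitters' processing notes, adapters were trimmed with cutadapt and the genome build was hg38; the aligner, the counting tool, the versions and the annotation are not given in the sources used here. The table gives all reads of an interval and no separate count of reads with T-to-C conversions, so the planned labelled share, labelled read decay, its gene lists and its relation to GC3 are not analysed here.

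The table has 122099 rows for 79184 transcripts. Rows with a transcript of GENCODE release 29 (GRCh38) held 98.14% of the reads, gene names and coordinates were taken from that release, and 8667 rows on alternate sequences had 0 reads. Many rows of a gene cover the same interval, and their plain sum counts reads 2.314 times on average, so overlapping intervals of a gene were collapsed to the one with most reads and the separate intervals were added. This replaced the plain sum that had been planned, which was kept as an alternative. Of 30681 genes with a row, 95 with counts identical to another gene's and 557 with a repeated symbol were left out, which left 30029. Genes whose last 300 bases share 50-base stretches with another gene are called uncertain where named. All columns of the table were used. Groups were taken from the sample titles. The table totals of the libraries ran from 17308748 to 30582204, and the gene totals from 7412941 to 12821783. No 2 replicates were the same library, since counts of every pair within a group differed by 2.893 to 6.937 times the sampling noise (chi-square per degree of freedom).

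Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on counts with TMM factors and filterByExpr, in 1 fit of all 18 libraries with a mean per group, and adjusted over 14956 genes by Benjamini-Hochberg, with a threshold of 0.05. The 7 comparisons were knockout against control over all times, at 0, 3 and 6 h, 6 h against 0 h in each genotype, and the interaction of genotype with time, 6 h against 0 h. CPM values use the TMM factors, with a prior count of 2 for log2 CPM. The SE of a fold change is its size over the square root of the F statistic. Simulated counts with 200 changed genes were used to test the fit. Over all times (14706 genes tested) it recovered 83.5% of genes changed 2-fold and 66.3% of those changed by log2 0.5, with 5.2% false calls, and at 0 h (14696 genes tested) 76.3% and 49.5%, with 3.2% false calls.

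Genes named in the text follow a rule fixed before the data were examined. It takes DHX29, then, among called genes with an official symbol, at least 5 CPM in mean and all knockout libraries on the same side of all control libraries at each time (or of the groups compared), the 10 largest rises and falls over all times and the 5 for other comparisons, and the 4 members with the smallest p in each gene list. A few genes that met the rule are not reported here. Chromosomes 4, 13 and 17, the boundary at 50 Mb, the stretch of chromosome 3, and the protocadherin and MT-RNR2-like genes were chosen after their values were seen.

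The 26 lists cover the integrated stress response, the unfolded protein response, cytosolic chaperones, p53 targets, interferon genes, immediate early transcripts, cytosolic ribosomal proteins, translation initiation factors, ribosome collision factors, mRNA decay factors, ZNF-named zinc finger genes, replication-dependent histones, nuclear-encoded oxidative phosphorylation, mRNAs of mitochondrial DNA, cholesterol synthesis, glycolysis, G2 and mitosis, S phase, ribosome biogenesis, hypoxia, pyrimidine metabolism, neuronal genes of HEK293, and markers of fibroblasts, blood cells, epithelia and hepatocytes. They were tested on voom values with limma's camera (correlation 0.01), adjusted over the 23 lists with at least 3 measured genes, with an estimated correlation and fry as alternatives. On simulated counts camera called a list of 30 genes shifted by log2 0.25 and none of 22 unchanged lists, with the preset and with the estimated correlation. Genes were simulated as independent, so this does not test lists whose genes move together, such as the ribosomal proteins (estimated correlation 0.246). GC3 was the share of G or C at the third codon position of the longest coding transcript. It was compared between genotypes as 1 value per library, by exact two-sided permutation of genotypes within times (8000 assignments), and across genes by Spearman's rho, also given the GC content of the last 500 bases. The same permutation was used for chromosome scores.

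The alternatives were DESeq2's size factors in edgeR, library totals, no low-count filter, a mean count of at least 10, the DESeq2 Wald test (DESeq2 1.42.0), the replicate number as a block, fits of only the groups compared, the plain sum of intervals, each interval on its own, and leaving out each library. For GC3 they were the slope over all genes, the annotation's principal transcript, a mean count of at least 10 and an adjustment for the 3′ end GC. Added after the data were seen were fits without chromosomes 4, 13 and 17, the interval with most reads per gene, protein-coding genes only, a mean of at least 5 CPM for the GC3 correlation, and leaving out each library for the lists and that correlation. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.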

Results

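The series set out to compare mRNA stability in human HEK293T cells with and without DHX29, a DExH-box helicase that helps the small ribosomal subunit scan structured leaders during translation initiation. Cells that express Cas9 carried either a control guide RNA or a guide against DHX29, and are called control and knockout below. RNA was labelled with 25 µM 4-thiouridine for 24 h, the label was chased with 2.5 mM uridine for 0, 3 or 6 h, and 3′ end libraries were sequenced. Each of the 6 groups held 3 replicates, which made 18 libraries, 9 per genotype. The values analysed were read counts per 3′ UTR interval over all reads, labelled and unlabelled together, so they measure how abundant a transcript was at each time and not how fast it decayed. Table totals ran from 17308748 to 30582204 reads, and once overlapping intervals were counted a single time the gene totals ran from 7412941 in control at 0 h, replicate 2, to 12821783 in control at 6 h, replicate 3. The tests covered 14956 genes, 13094 of them protein-coding. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

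DHX29 itself (ENSG00000067248, GRCh38 chromosome 5, 55256245 to 55307722, minus strand) was lower in knockout. Its 3′ UTR reads averaged 11.89 ± 1.49 CPM in control and 7.19 ± 1.25 CPM in knockout (SD, n = 9 each), and the fitted fold change over all times leaves 60.1% of the control level. The lowest control library stood at 9.42 CPM and the highest knockout library at 8.92 CPM, from 50 to 171 reads per library. Over all 3 times the log2 fold change was -0.73 (SE 0.11, adjusted p = 2.34e-06, edgeR quasi-likelihood test). By time it was -0.80 at 0 h (adjusted p = 0.0158), -0.88 at 3 h (adjusted p = 0.00343) and -0.51 at 6 h, where it missed the threshold (adjusted p = 0.116). The call at 0 h was lost without control replicate 2 (-0.75) or knockout replicate 2 (-0.67), and the call at 3 h without knockout replicate 2 (-0.71). The site the guide targets is not given in the sources used here, and a 3′ tag lies away from many coding edits, so the read count checks the label only weakly and does not measure DHX29 protein.

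**Figure D1:**
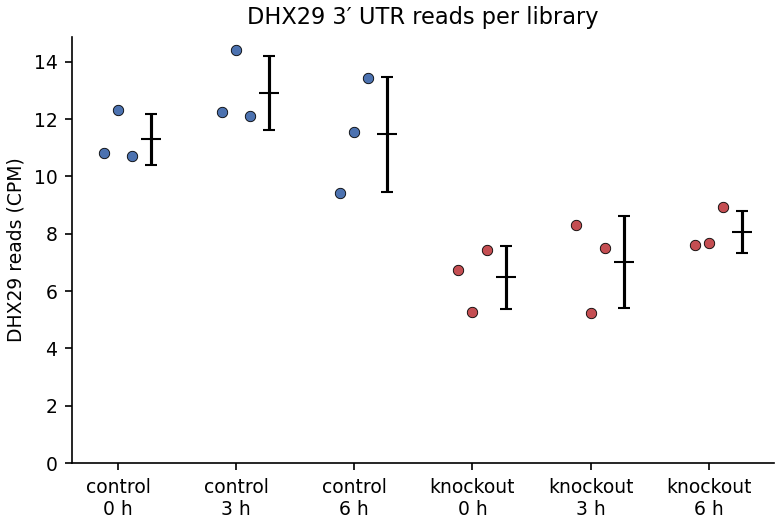
DHX29 3′ UTR reads in CPM (vertical axis) for each of the 18 libraries (points), by genotype and hours of chase; the line with bars beside each group is its mean ± SD, n = 3. All 9 knockout libraries lie at or below 8.92 CPM and all 9 control libraries at or above 9.42 CPM.

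The comparison of knockout with control over all 3 chase times asked which transcripts differed in abundance whatever the time. The largest rises among well-measured genes were in RPRM, which encodes the p53-induced cell cycle arrest protein Reprimo, from 6.85 ± 1.71 to 33.39 ± 4.00 CPM (4.93-fold, n = 9 each), in BASP1, a membrane-associated growth cone protein (3.70-fold), in the transcription factor CEBPD (3.40-fold) and in CDKN1C, the cyclin-dependent kinase inhibitor p57 (2.91-fold). SNX19 (2.31-fold), the orphan receptor GPR37 (2.15-fold), the retinoic acid-synthesising enzyme ALDH1A2 (2.13-fold, from 12.59 ± 1.60 to 26.8 ± 3.01 CPM) and the neuroendocrine transcription factor INSM1 (2.01-fold) were also higher. PCDH10, a protocadherin gene on chromosome 4 (2.22-fold), and ATP1B2, a sodium pump subunit gene on chromosome 17 (1.93-fold), lie on chromosomes whose genes as a whole were higher, as described below. The deepest fall was in the solute carrier gene SLC45A4, from 57.16 ± 5.29 to 13.97 ± 1.37 CPM (log2 fold change -2.03, SE 0.07, adjusted p = 3.05e-29). HSPA1A, an inducible heat shock protein 70 gene, was lower with log2 -1.20, from 14.68 ± 3.29 to 6.46 ± 1.94 CPM. The transcription factor RUNX1 (-1.12), the synaptic adhesion gene NRXN3 (-1.10), the ephrin receptor EPHB1 (-0.94), the cancer-testis antigen MAGEA1 (-0.89), MAL2 (-0.88) and FAM133A (-0.74) followed on the log2 scale. NALF1 (-0.83) is on chromosome 13, whose genes as a whole were lower. The fall of HSPA1A does not stand for heat shock protein 70 mRNA in general. HSPA1B, another heat shock protein 70 gene, had far more reads and fell less, by log2 -0.24, from 829.8 ± 231 to 693.4 ± 160 CPM.

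In all, 2161 of 14956 genes (14.4%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1049 higher and 1112 lower in knockout. Most changes were small, with a median size of log2 0.24 among the called genes, and 94 higher and 20 lower genes exceeded 2-fold. With library totals in place of TMM factors the split was 1368 higher and 777 lower, so the balance between the directions depends on the scaling. Without the genes on chromosomes 4, 13 and 17, a setting chosen after the data were seen, 1464 genes passed, 683 higher and 781 lower.

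**Figure D2:**
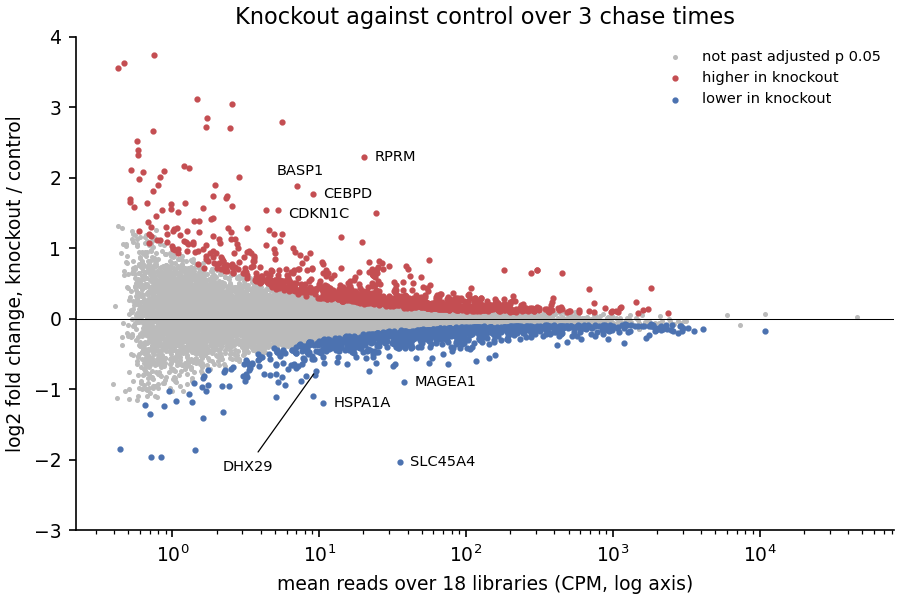
Each point is 1 of 14956 genes, with its mean reads in CPM over 18 libraries (log axis) against its log2 fold change, knockout over control, averaged over 3 chase times. Red and blue mark the 1049 higher and 1112 lower genes past an adjusted p of 0.05; RPRM and SLC45A4 stand out at 2.30 and -2.03.

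The called genes were not spread evenly over the genome. Among genes with at least 5 CPM, those on chromosome 17 had a median log2 fold change of 0.12 and 87.0% were above 0, and 259 of its 933 tested genes were higher against 11 lower. On chromosome 4 the median was 0.11, with 129 of 534 genes higher and 10 lower, and it came from the part beyond 50 Mb (0.15, 251 genes) and not from the part before (-0.002, 116 genes). On chromosome 13 the median was -0.20, with 102 of 273 genes lower and 6 higher. The other chromosomes had medians of at most 0.046 in size, chromosome 5 with DHX29 among them (-0.012), though a stretch of chromosome 3 between 20 and 60 Mb stood at -0.13 (190 genes) against -0.008 elsewhere on it. These 3 chromosomes held 517 of the called genes (23.9%), and chromosomes 4 and 17 held 37% of the higher genes with 9.8% of the genes tested. The knockout and control libraries were apart at every time on these 3 chromosomes, and the exact two-sided permutation of genotypes within times gave p = 0.00025 for each, the smallest value it can give, or 0.000958 adjusted over 23 chromosomes. The same separation and the same p held for the smaller shifts of chromosomes 3 (-0.035), 9 (-0.033) and X (-0.046), and chromosomes 2, 8, 14 and 20 also passed adjusted, so size and not the p-value sets 4, 13 and 17 apart. The 3 chromosomes and the 50 Mb boundary were picked after their values were seen.

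**Figure D3:**
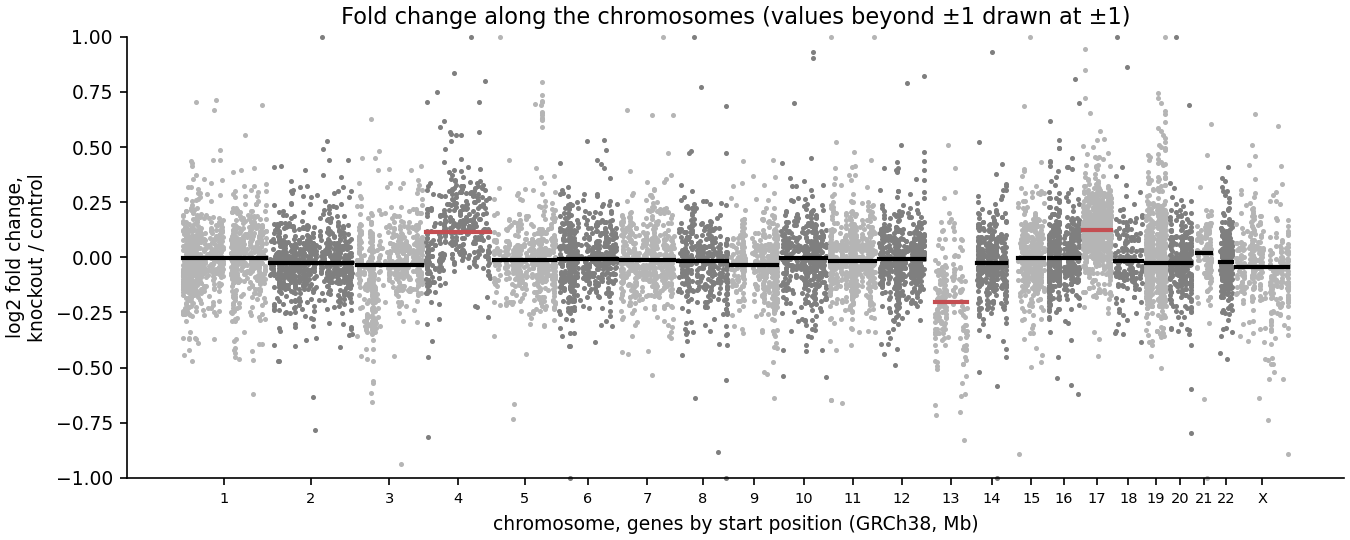
Log2 fold change, knockout over control, of genes with at least 5 CPM (points) by position along chromosomes 1 to 22 and X (GRCh38, Mb), with values beyond 1 in size drawn at the edge. Bars are chromosome medians, and the red bars mark chromosomes 4 (0.11), 13 (-0.20) and 17 (0.12).

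**Figure D4:**
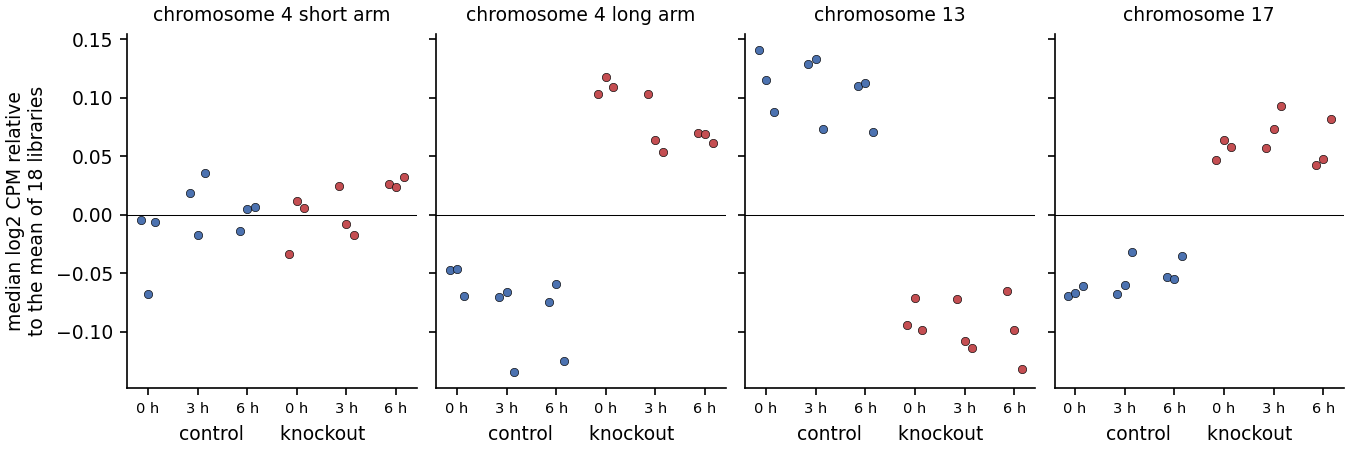
Median log2 CPM of the genes of a region relative to their mean over 18 libraries (vertical axis), 1 point per library, by hours of chase in control (blue) and knockout (red). The short arm of chromosome 4 is given by genes starting before 50 Mb and the long arm by the rest; all libraries of the genotypes are apart on the long arm of 4, on 13 and on 17, and mixed on the short arm.

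Among the 26 gene lists fixed before the data were examined, 23 had at least 3 measured members, and 10 passed limma's camera test with a preset correlation of 0.01, 4 higher and 6 lower. The p53 targets, zinc finger genes and translation initiation factors also passed with an estimated correlation between genes, and the other 7 did not. The 6 lower lists had median levels of 127 to 1080 CPM, and the 4 higher lists 2.21 to 27.8 CPM. Abundant genes were slightly lower in general. Outside the shifted chromosomes, the most abundant of 3 expression classes had a median of -0.033 and the least abundant 0.004. Only the ribosomal list was compared with genes matched on level. For the other lists, level was thus not separated from function. Of 18 p53 targets, 7 rose, none fell and 11 did not pass, or 11 rose adjusted over the list alone, with a median log2 fold change of 0.16 (adjusted p = 7.61e-05, and 0.0103 with an estimated correlation). MDM2, the ubiquitin ligase of p53, rose by log2 0.24 (182.8 ± 17 to 215.1 ± 18.7 CPM, n = 9), CDKN1A, which encodes the kinase inhibitor p21, by 0.24, the death receptor gene TNFRSF10B by 0.23 and ZMAT3 by 0.22. Of 421 ZNF-named zinc finger genes, which encode mostly DNA-binding proteins, 83 rose and 8 fell (95 and 11 adjusted over the list alone), with a median of 0.11 (adjusted p = 7.24e-07, and 0.0106 with an estimated correlation). ZNF605 (0.82) and ZNF829 (0.75) were well measured, ZNF793 rose 6.53-fold from 0.673 ± 0.39 CPM, and ZNF286A (0.36, uncertain because its 3′ end is shared with other genes) is on chromosome 17; 15 list members are on chromosomes 4, 13 and 17. Of 40 translation initiation factors 13 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.065 (adjusted p = 0.000586, and 0.0379 with an estimated correlation). EIF2D (-0.23), EIF2A (-0.22) and the cap-binding homologue EIF4E2 (-0.17) fell, and the start-codon selection factor EIF1, on chromosome 17, rose by 0.11.

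Cytosolic ribosomal protein mRNAs fell in 43 of 83 cases and rose in 2 (53 and 4 adjusted over the list alone), by a median of -0.086 (adjusted p = 5.57e-22, and adjusted p = 0.0729 with an estimated correlation). RPL10 (-0.19) and RPL13A (-0.16) fell, as did RPL29 (-0.29), in the lower stretch of chromosome 3, and RPL21 (-0.33), on chromosome 13; both share 3′ sequence with other genes and are uncertain. Genes of oxidative phosphorylation fell in 14 of 77 cases and rose in 1 (17 and 2 adjusted over the list alone), with a median of -0.054 (adjusted p = 0.00029, and adjusted p = 0.241 with an estimated correlation). ATP5MC2 and NDUFA7 fell by 0.18 and 0.19 on the log2 scale, and NDUFC1, on chromosome 4, rose by 0.28. Of 19 glycolysis genes 7 fell and none rose, 7 and 0 also adjusted over the list alone, among them ENO1 (-0.23) and HK1 (-0.29), with a median of -0.048 (adjusted p = 0.000586, and adjusted p = 0.173 with an estimated correlation). Of 25 ribosome biogenesis genes 5 fell and none rose, as over the list alone, with FBL, the methyltransferase fibrillarin, at -0.22 and BOP1 at -0.25, and with GNL3 (-0.20) and RRP9 (-0.31) in the lower stretch of chromosome 3 (list median -0.029, adjusted p = 0.0449, and adjusted p = 0.233 with an estimated correlation). Of 15 cytosolic chaperones 4 fell and none rose (4 and 1 adjusted over the list alone, median -0.029, adjusted p = 0.0265, and adjusted p = 0.173 with an estimated correlation), among them HSPH1 (-0.23), on chromosome 13. Under library totals the medians of these lists moved towards 0, to -0.06 for ribosomal proteins, -0.028 for oxidative phosphorylation, -0.022 for glycolysis and -0.003 for ribosome biogenesis and for chaperones, and that of the initiation factors to -0.039. Without the genes on chromosomes 4, 13 and 17, 1 of them a chaperone, the chaperone call was lost (adjusted p = 0.12) while the median moved little, to -0.023, with 3 of 14 genes lower.

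Immediate early and short-lived transcripts rose in 10 of 31 cases and fell in 1 (13 and 1 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0019, and adjusted p = 0.174 with an estimated correlation). The kinase gene SGK1 rose 1.45-fold, the AP-1 subunit gene JUNB 1.37-fold, EGR1 1.62-fold and SNAI1 2.25-fold, the last from 1.25 ± 0.711 CPM. The rise of EGR1 came from 3 h (6.86 to 24.71 CPM), against 4.00 and 3.88 CPM in control and knockout at 0 h and 4.42 and 5.42 CPM at 6 h. Of 16 interferon and innate immune genes 2 rose, as over the list alone, IFITM3 (2.19-fold, uncertain because of shared 3′ sequence) and IFI6 (1.35-fold), and none fell (median 0.24, adjusted p = 0.0378, and adjusted p = 0.104 with an estimated correlation). The median levels of that list were low, at 2.21 CPM.

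The remaining lists did not pass. Of 29 integrated stress response genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.665), with ATF4 itself at -0.19 (uncertain, with shared 3′ sequence), the glutathione-degrading enzyme CHAC1 at 0.69 and SLC7A1, on chromosome 13, at -0.28. The unfolded protein response list had 1 higher and 4 lower of 16 (2 and 4 over the list alone), with a median of 0.007, a mean of -0.018 and a test that pointed down (adjusted p = 0.343). Ribosome collision and no-go decay factors had 2 higher and 3 lower of 22 (adjusted p = 0.343), with a median of -0.025 that became 0.001 under library totals. The deadenylation, decapping and decay factors had 1 higher and 3 lower of 39 (0 and 1 adjusted over the list alone, adjusted p = 0.265), with CNOT10, a subunit of the CCR4-NOT deadenylase, at -0.27, in the lower stretch of chromosome 3. Replication-dependent histones had 3 lower and none higher of 21 (adjusted p = 0.143), among them H2AC25 at -0.39. The list of G2 and mitosis had 5 lower and 1 higher of 27 (adjusted p = 0.111, and 0.0356 without chromosomes 4, 13 and 17), with UBE2C at -0.22 and CDK1 at -0.16. DNA replication and S phase had 2 lower and 1 higher of 26 (adjusted p = 0.21), with MCM4 at 0.24 and RRM2 at -0.21. Cholesterol synthesis had 3 higher and 1 lower of 23 (adjusted p = 0.539), led by SC5D at 0.44. The hypoxia list had 1 of 15 higher (adjusted p = 0.539). Uridine and pyrimidine metabolism had 2 higher, NME1 and NME2 on chromosome 17 (NME2 uncertain, with shared 3′ sequence), and 2 lower of 18 (3 and 4 over the list alone, adjusted p = 0.88 by camera). Its median was 0.004, or -0.028 without chromosomes 4, 13 and 17, and its mean -0.018. The neuronal genes that HEK293 cells express had 3 lower of 9, NEFL at -0.35, NCAM1 at -0.33 and GAP43 at -0.45 (adjusted p = 0.0784). Among markers of other cell types, 1 of 5 fibroblast genes was higher, COL1A1 on chromosome 17 (list adjusted p = 0.161), as was 1 of 3 epithelial genes (adjusted p = 0.161). The blood cell gene CD14 stayed below 1 CPM in mean and, like the 2 hepatocyte genes, did not pass. None of the mRNAs encoded by mitochondrial DNA was measured.

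At the single times, among genes that met the naming rule, RPRM, CEBPD and BASP1 were among the 5 largest rises and SLC45A4 and HSPA1A among the 5 largest falls each time. RPRM was 4.25-fold higher at 0 h, 4.97-fold at 3 h and 5.65-fold at 6 h (35.61 ± 3.59, 35.64 ± 1.74 and 28.93 ± 1.79 CPM in knockout, n = 3 each), and SLC45A4 stood at log2 -2.01, -2.07 and -2.03. The immediate early transcription factor EGR1 was higher at 3 h, 24.71 ± 10.8 against 6.86 ± 2.41 CPM (log2 1.86, adjusted p = 2.12e-06 by edgeR). FAM24B ranked among the largest rises at 3 h (1.64), PCDH10 at 6 h (1.57), and CRMP1, a neuronal cytoskeleton gene, among the largest falls at 6 h (-1.14). These 3 genes differed in the same direction at the other times too. FAM24B stood at 6.32 CPM in knockout against 2.88 in control at 0 h, and CRMP1 at 4.79 against 9.22 at 3 h. Some other genes at the top of a single time lost their call when 1 library was left out. Their fold changes often moved little, and fits with fewer samples call fewer genes. At 0 h the call of ZSCAN18 (1.41) was lost without control replicate 3 (1.13), that of HYAL3 (-1.05, in the lower stretch of chromosome 3) without control replicate 2 (-0.90), and that of NALF1 (-1.09) without control replicate 1 (-1.08), control replicate 2 (-1.02), knockout replicate 2 (-0.88) or knockout replicate 3 (-1.06). At 3 h the call of EPHB1 (-1.18) was lost without knockout replicate 1 (-0.97) and that of RUNX1 (-1.04) without control replicate 1 (-0.87), knockout replicate 1 (-1.03) or knockout replicate 2 (-0.925). At 6 h the call of MAL2 (-0.94) was lost without control replicate 2 (-0.805) or knockout replicate 3 (-0.79).

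With 3 libraries against 3, edgeR's quasi-likelihood test called 160 higher and 149 lower genes at 0 h, 213 and 189 at 3 h and 248 and 305 at 6 h. With library totals as the scaling, the split was 217 higher and 99 lower at 0 h and 373 and 164 at 6 h. Leaving out control replicate 1, control replicate 2 or knockout replicate 3 at 0 h left 199, 202 and 199 calls. At 3 h, 239 calls were left without control replicate 2, 232 without knockout replicate 1 and 227 without knockout replicate 2. At 6 h, 353 were left without control replicate 1, 342 without control replicate 3, 319 without knockout replicate 1 and 324 without knockout replicate 2. Without chromosomes 4, 13 and 17 the counts were 198 at 0 h and 246 at 3 h, and with the plain sum of intervals 249 at 3 h and 334 at 6 h. The lists of different times share no libraries. At 0 and 3 h, 97 genes were higher in both and 75 lower in both, where independent lists of these sizes would share 2.3 and 1.9. At 0 and 6 h the shared numbers were 100 and 94, against 2.7 and 3, and at 3 and 6 h 105 and 90, against 3.5 and 3.9. No gene was called in opposite directions in any of these pairs, and 143 genes were called at all 3 times, 83 higher and 60 lower.

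The comparison of 6 h with 0 h within each genotype shows what the chase and its medium change went with in total reads. CCN1 and CCN2, which encode secreted matricellular proteins and are known targets of the growth regulator YAP, rose most. In control CCN1 went from 3.88 ± 1.35 CPM at 0 h to 32.58 ± 6.23 at 3 h and 25.61 ± 2.32 at 6 h (n = 3 each), 6.75-fold at 6 h, and in knockout from 5.22 ± 0.811 to 32.06 ± 5.01 CPM, 6.08-fold. CCN2 rose 6.94-fold in control and 6.90-fold in knockout. The cytokine receptor gene TNFRSF12A (2.30-fold) and TRAPPC11 (2.31-fold) were among the largest rises in control, and ARC (2.44-fold), the AP-1 subunit gene FOSL2 (2.12-fold) and EPPK1 (2.26-fold) in knockout. PCDH10 fell by 1.35 on the log2 scale in control, from 13.19 ± 1.24 to 5.17 ± 0.494 CPM, SCRG1 by 1.20 in control and 1.47 in knockout, the transcription factor gene SP9 by 1.36 and 1.13, JAZF1 by 1.14 in control and NFATC4 by 1.06 in knockout. OR2L2, TIMM23B-AGAP6 and NMNAT3, which also met the naming rule, share 3′ sequence with other genes, and their changes are uncertain.

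**Figure D5:**
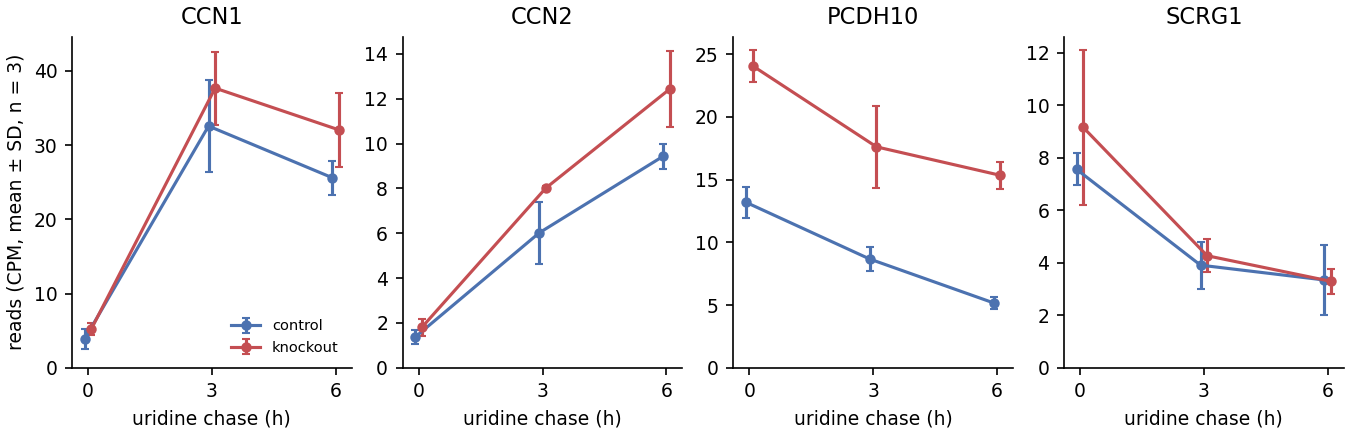
Reads in CPM (vertical axes, mean ± SD, n = 3) of CCN1, CCN2, PCDH10 and SCRG1 after 0, 3 and 6 h of uridine chase in control (blue) and knockout (red). CCN1 and CCN2 rose and SCRG1 fell in both genotypes, and PCDH10 was higher in knockout throughout.

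In control 1107 genes were higher and 911 lower at 6 h than at 0 h, and in knockout 1060 and 919, by edgeR's quasi-likelihood test at an adjusted p of 0.05. With library totals the splits were 1389 and 740 in control and 1423 and 624 in knockout. Leaving out knockout 0 h replicate 1 left 1275 calls in knockout, and each interval tested on its own gave 3169 calls in control and 3185 in knockout. Without shared libraries, 657 genes rose in both genotypes and 488 fell in both, where independent lists would share 78.5 and 56, and none went in opposite directions. Fold changes correlated across genes with r = 0.488, where genes are not independent replicates. By camera, in tests added after the data were seen, ribosomal protein mRNAs fell over the chase in control (11 of 83 lower, 1 higher, adjusted p = 0.0116) and in knockout (34 lower, none higher, adjusted p = 1.02e-19), and S phase genes rose in control (8 higher and 1 lower of 26, adjusted p = 0.0116) and in knockout (adjusted p = 0.00606). Ribosome biogenesis genes rose in control (8 higher and none lower of 25, adjusted p = 0.0123) and did not pass in knockout (4 higher and 1 lower, adjusted p = 0.338), a difference not tested as such for the list. None of these calls held with an estimated correlation, where the adjusted p of the ribosomal list was 0.626 in control and 0.39 in knockout and those of the S phase and ribosome biogenesis lists were 0.411 in control. Under library totals the ribosomal median over the chase moved towards 0, from -0.044 to -0.014 in control and from -0.122 to -0.074 in knockout. Whether the change from 0 to 6 h differed between genotypes was tested directly as the interaction of genotype with these 2 times; the change to 3 h was not tested this way. No gene passed by edgeR (smallest adjusted p = 0.786) or by DESeq2. Of the 14956 genes tested, 571 had an unadjusted p under 0.05 in edgeR, no more than that threshold gives by chance. The simulations did not cover the interaction, whose SE was larger (for DHX29 0.273, against 0.111 over all times). The lack of calls thus does not show that the genotypes changed alike.

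Codon usage at the third codon position is a known correlate of mRNA stability in human cells, which is why G or C at that position (GC3) was set against the change in knockout. Genes with low GC3 did not move detectably against genes with high GC3 when the library was the unit, in a test that left out the replicate number. The mean log2 CPM of the fifth of protein-coding genes with the lowest GC3 minus that of the fifth with the highest was 0.0323 higher in knockout than in control (exact two-sided permutation within times, p = 0.186, where the smallest possible is 0.00025). By time the difference was 0.0335 at 0 h, 0.0033 at 3 h and 0.06 at 6 h, with exact p of 0.4, 1 and 0.4, where 3 against 3 cannot go below 0.1. Across 13014 genes, which are not independent replicates, GC3 correlated weakly with the log2 fold change (Spearman's rho -0.083). Without control 6 h replicate 3 that rho was -0.047 and the difference between low and high GC3 genes 0.0185. Genes higher in knockout had a median GC3 of 54.8%, genes lower 62.8% and all tested genes 59.0%. The GC content of the last 500 bases of the transcript, which correlated with GC3 (rho 0.657), had a rho of -0.094 with the fold change, that of the 5′ UTR had a rho of -0.107, and with the 3′ end GC held fixed the rho of GC3 was -0.028. Adjusted for the 3′ end GC, the difference between the low and high GC3 genes was -0.0017 (exact permutation p = 0.764). The replicate number was used as a block only with this adjustment. The unadjusted score varied widely between replicates, at 1.0342, 1.0019 and 0.8942 in replicates 1, 2 and 3 of control at 6 h. Because the unadjusted difference of 0.0323 was not tested with the block, its permutation p of 0.186 does not show that the genotypes were alike.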

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

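The fits without chromosomes 4, 13 and 17, with the interval with most reads per gene, with protein-coding genes only and at 5 CPM or more, and the lists and GC3 correlation without each library, were chosen after the data were seen. No result past its threshold reversed. Of those not past it, several changed sign. Among them, the GC3 difference turned from 0.0323 to -0.0017 with the 3′ end GC adjusted, and the median of the ribosome collision list from -0.025 to 0.001 under library totals. The median of the uridine and pyrimidine list turned from 0.004 to -0.028 without chromosomes 4, 13 and 17. Counts stayed within 1.5 times of their main value except as follows. The plain sum of intervals left 249 calls at 3 h and 334 at 6 h, and the cause was not tested; each interval on its own gave 3169 over the chase in control and 3185 in knockout, where more features were tested. Without the 3 chromosomes 198 calls were left at 0 h and 246 at 3 h, where fewer genes were tested. With the replicate number as a block there were 492 calls at 0 h, 649 at 3 h and 937 at 6 h (2591 over all times), and the cause was not tested. The labels do not say what the numbers stand for. Correlations of 45 pairs with the same number were small, from -0.034 to 0.097, with a median of 0.029 against -0.014 for other numbers. Still, 15 of 18 libraries were closest to their own number, and in every group replicates 1 and 2 differed less from each other than from replicate 3. The data thus hold a grouping by number, which the main fits do not model and the design does not explain. Its correlations were small, but more genes were called once it was modelled. The block changed no list count (10), and with it and the 3′ end GC the GC3 difference was -0.0017. Of the lists, 3 passed with an estimated correlation, 16 by fry for direction and 21 by fry for either direction. A call lost with an estimated correlation need not mean that the genes move together. The interferon list had an estimate of -0.009, below the preset 0.01, and its adjusted p by camera still rose from 0.0378 to 0.104. The fry test does not compare a list with other genes. The rho of GC3 was -0.028 given the 3′ end GC.

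Leaving out 1 library gave 1890 to 2098 calls over all times, 199 to 234 at 0 h, 227 to 293 at 3 h, 319 to 486 at 6 h, 1371 to 1615 over the chase in control, 1275 to 1843 in knockout and 0 for the interaction; fits with fewer samples call fewer genes. DHX29 ranged from -0.78 to -0.68, the lists from 8 to 11, the GC3 difference from 0.0185 to 0.0418 and the rho from -0.104 to -0.047. Of 3947 values for 169 named gene results, 3859 stayed on their side of the threshold, 78 lost the call and 10 gained it, and all 540 for the 20 largest changes over all times kept it. Of 115 list values, 89 stayed, 8 lost and 18 gained the call. Over all times, a fit of only the groups compared is the fit itself. The alternatives planned for labelled reads (offsets, filters, time as a line, DESeq2, block, left-out libraries, conversions per T, estimated correlation, 3′ end content) were not run. On simulated counts 66.3% of changes of log2 0.5 were recovered over all times and 49.5% at 0 h; depth alone was not varied.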

Other observations

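The gene families of the next paragraph, the test of a few strongly changed genes, the test of 3′ end GC against GC3 and its bound of 0.03, and the test of single times for GC3 were chosen after the results were seen. The tests of expression classes for copy number took the place of a comparison of the arms of chromosome 4, because that boundary had already been seen. The first paragraphs give biology that no comparison above covers.

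Some clustered protocadherins, cell adhesion genes on chromosome 5 that neurons express in varied combinations, were higher in knockout over all times; no list test was run on them. Of 9 measured beta genes 6 rose and none fell (edgeR, median log2 2.85), and their mean level went from 0.392 ± 0.0846 CPM in control to 1.61 ± 0.218 CPM in knockout (SD, n = 9 each), with the lowest knockout library at 1.32 and the highest control library at 0.555. PCDHB2 rose from 0.592 ± 0.453 to 4.46 ± 1.08 CPM and PCDHB16 from 0.415 ± 0.235 to 3.03 ± 1.33 CPM. All 13 gamma genes rose (median 0.65, from 18.8 ± 1.46 to 29.9 ± 2.17 CPM), but they share their last exons and so nearly the same reads, which makes them 1 signal. None of 4 alpha genes passed. The directions were the same under each scaling.

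Nuclear genes that resemble the mitochondrial 16S ribosomal RNA (MT-RNR2-like) rose in 6 of 7 cases, with a median of 0.66 and a mean level of 176 ± 17 CPM in control and 277 ± 27.4 CPM in knockout. Their sequence is close to that of MT-RNR2, which did not pass itself (0.02, adjusted p = 0.874 by edgeR), as MT-RNR1 did not (0.07), so the source of these reads is uncertain. MTRNR2L3 and MTRNR2L11 had nearly the same counts, with 21316 and 21270 reads in control and 31714 and 31654 in knockout. The 6 rises may thus rest on shared reads and should not be counted as 6 separate signals.

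The chromosome-wide shifts on 4, 13 and 17 were weighed first. A few strongly changed genes are excluded, as 87.0% of chromosome 17 genes had a positive fold change, and so are GC content, length and expression level as the whole cause, since the chromosome 17 median was 0.141 after adjustment for them. A different copy number in the cell populations needs a shift at every level of expression, and the smallest of the medians over 3 expression classes in each region was 0.110, in the direction of its chromosome. Nearly all genes of these regions shift 1 way, so that test could hardly come out otherwise and lends no support, and copy number stays an open hypothesis, since no DNA was measured. Whether such a difference came with the knockout or from the separate history of the cell populations was not tested.

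Lower ribosomal protein mRNAs in knockout were weighed next. To weigh a fall of all abundant transcripts, 10000 random lists matched on expression were drawn. Their medians centred on -0.046, with the lowest 2.5% below -0.063 and the lowest at -0.087, against -0.086 for the 83 genes. The 83 genes move together (estimated correlation 0.246), which random genes need not, so these medians spread too little to exclude that fall. The matched median is in any case part of the change. The shifts of the 3 chromosomes weighed above are excluded as the cause, since the median on the other chromosomes was -0.093. Smaller falls stayed in that test, such as the lower stretch of chromosome 3 (-0.129), which holds RPL29, and chromosome X (-0.046), which holds RPL10. Their part in the fall was not tested. As for a single time, the mean of the 83 genes per library was lower in knockout at each time. The genotypes were apart at 0 h (-0.0668) and 6 h (-0.149) and overlapped at 3 h (-0.0232). Exact permutation gave p = 0.1 at 0 and 6 h, the smallest possible, 0.5 at 3 h and 0.003 over the times. In these libraries the fall was thus not confined to 6 h. The joint test was not run without 6 h, so a leading part of that time is not excluded. An effect of the loss of DHX29 on these mRNAs may remain, but a difference between the cell populations as such was not tested, and the list did not pass with an estimated correlation.

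The relation of fold change to GC3 was weighed last. It did not come from chromosomes 4, 13 and 17, since the rho without them was -0.102. As for a single time, rho was -0.078 at 0 h, -0.011 at 3 h and -0.103 at 6 h, so it was below -0.03 at 2 of the 3 times; the test first asked for all 3 times, which would have left it open, and was loosened to 2 once these values were known. Most of it was lost once the GC content of the transcript's 3′ end was held fixed, where rho went from -0.083 to -0.028, and to -0.034 without the 3 chromosomes, values on either side of the bound of 0.03. A bias of 3′ end tags with GC content may thus account for part of the relation, but GC3 and 3′ end GC are correlated and the GC content of the 5′ UTR had a larger rho with the fold change (-0.107), so the 3′ end is not singled out, and codon usage or the leader as a biological cause stays open.

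Other splits of the same libraries were fitted to see how many genes they call. For knockout against control over all times, 1 of 100 splits within times, the real one, gave as many calls as the real 2161, the highest other giving 236 and the next 1. A random division of these 18 libraries thus hardly gives as many calls. The splits cannot exclude a chance difference between the cell populations, since all libraries of a genotype would share it. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of these comparisons 1 of 10 splits, the real one, gave as many calls, with 309 against at most 7 at 0 h, 402 against 2 at 3 h, 553 against 1 at 6 h, 2018 against 0 over the chase in control and 1979 against 1 over the chase in knockout. For the interaction of 6 h against 0 h the real count was 0, which all 100 of 100 splits reach whatever the data, so this comparison says nothing about chance. The highest other split called 176 genes, in a split that swapped most genotypes at 0 h and none at 6 h, so that it carries the genotype difference itself.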
